A study of Mesocricetus auratus with 24 samples.

How the data were processed

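Reduced representation bisulfite libraries from 24 samples were used, 4 in each of 6 groups, with groups and replicate numbers taken from the sample labels. Per the labels' protocols, libraries were prepared from genomic DNA with a commercial kit. Per the submitters' processing notes, bcl2fastq 2.20.0.42, Trim Galore 0.5.0, Bismark 0.22.1, Bowtie2, R 3.6.1 and methylKit 1.10.0 were used, with no role or setting given. The genome build is not given in the sources used here. The coordinates are those of the deposited files.

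Per the file headers, the authors' tables give for each CpG position and strand the read coverage as a count, and the percent of those reads that carried C (methylated) or T (unmethylated). The deposited coverage is an unnormalised count and no position below 10 reads is listed. Methylated reads were recovered as coverage times percent over 100. At coverage up to 1000, 100% of the products lay within 0.06 reads of a whole number. The deposited counts do not show whether PCR copies were removed, so they may include them. Positions of low coverage were absent before any filter used here. Total coverage and the positions listed differed between libraries, which limits shared positions more than shared windows.

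Positions with at least 10 reads and outside the top 0.1% of coverage in their library were summed over windows of 1 kb. A window was tested when each of the 8 libraries had at least 3 such positions, not necessarily the same ones, and pooled methylation was 5 to 95%. The test was a quasi-binomial logistic model of methylated and unmethylated reads with group as the term. Pearson dispersions were squeezed with the empirical Bayes method of limma within 10 classes of pooled methylation, with a floor of 1, and followed by an F test and Benjamini-Hochberg adjustment. A window was called at an adjusted p below 0.05 with group means at least 10 percentage points apart. Reads per window are coverage summed over positions, so a read over several positions counts once for each. The median window had 293 to 336 such counts per library and a dispersion of 23.82 to 39.12. Replicates, technical ones included, thus differed by more than independent binomial counts give. Repeated counts of the same read and differing positions between libraries can add to this dispersion, so it does not measure replicate differences alone.

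Mean methylation per library was the unweighted mean over positions with at least 10 reads in all 24 libraries, without the upper limit on coverage. It was compared by an exact two-sided permutation test over 70 assignments, adjusted over the 3 comparisons. Windows were also split into quartiles of the number of CpG positions measured per window, strands counted apart, called CpG density here. This number depends on the positions covered as well as on the sequence. The windows named are, for each comparison, the 5 called windows with the largest increase and the 5 with the largest decrease whose groups did not overlap, or the 5 with the smallest p where none was called. By chance 2.86% of windows have groups that do not overlap. These rules, the tests and the alternatives were fixed before the data were examined. The coverage comparison, the classes by level in other libraries, the Fisher tests of the densest quartile, its comparison over all measured windows, the Fisher test of the lower-coverage scaffolds, and the alternatives of positions shared by the 8 libraries and of leaving out the lower-coverage scaffolds, were chosen after seeing the data.

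Coverage was compared between scaffolds with at least 200 positions in each of the 8 senescent and bypass libraries, as the share of a library's reads, centred on the median scaffold. Scaffolds with a log2 ratio below -0.5 were taken as lower. Bins of 250 kb with at least 50 positions were used to place the change inside a scaffold.

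The window test was tried on simulated windows with the real coverage and levels, drawn independently of each other. In each comparison 100 windows were changed by 20 points and 100 by 40. The simulated dispersions were the squeezed values from the main test, which vary less between windows than the raw ones. False calls and recovery may therefore favour the main test over other tests. Unchanged windows had p below 0.05 in 5.86%, 5.81% and 5.78% of cases for the pools, the colonies and the bypass comparison. The share of false calls was above the 5% that the adjustment aims at. It was 5 of 45 calls (11.1%) for the pools, 8 of 50 (16%) for the colonies and 6 of 67 (9%) for the bypass comparison, so adjusted p-values near 0.05 are somewhat too small. Changes of 40 points were recovered in 35%, 36% and 45% of windows and those of 20 points in 5%, 6% and 16%. edgeR's quasi-likelihood test made 0 false calls in each and recovered 2%, 0% and 4% of changes of 40 points.

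Samples of each group were compared pair by pair. No pair agreed within the noise of independent binomial counts. The lowest mean chi-square per window, with 1 degree of freedom, was 21.55, which repeated counts of the same read can also raise. All 24 libraries were kept. Library numbers were not used to pair samples. Promoter tests and gene lists fixed beforehand were not run, since the annotation at hand belongs to assembly BCM_Maur_2.0 and the coordinates use other sequence names. Calculations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The alternatives were another coverage minimum, no upper limit, other windows or single positions, other thresholds, other treatments of dispersion, edgeR, thinned reads, a replicate block and leaving out each library.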

Results

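Cytosine methylation was measured by reduced representation bisulfite sequencing, which reads CpG-rich fragments after unmethylated cytosines have been converted, in Syrian hamster fetal cells taken through a cell transformation assay. In that assay, fetal cells are seeded to form colonies, exposed to a chemical, and scored for colonies with altered morphology. The chemical was benzo[a]pyrene (B[a]P), a polycyclic aromatic hydrocarbon that cells convert into DNA-damaging metabolites, at 5 µg/mL. The 24 libraries fell into 6 groups of 4. Pools of about 60 colonies were collected on day 9 after B[a]P or after vehicle (0.2% DMSO). Cultures grown for 19 to 25 days came from B[a]P-treated colonies of transformed or of normal morphology. A culture derived from a transformed, B[a]P-treated colony was sampled on day 48, in senescence, and on day 94, after senescence had been bypassed. The pools and the colonies were described as biological replicates and the senescent and bypass libraries as technical replicates, so p-values for the last comparison measure technical spread in 1 culture at each time and do not extend to other cultures.

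Each library held between 809562 and 1484688 CpG positions, with strands listed apart, and a median coverage per position of 21 to 38 reads. Coverage summed over positions ran from 39858141 to 52772391 in senescent and from 35033371 to 48909677 in bypass libraries. It ran from 46741884 to 67276906 in transformed colonies, 42938360 to 63550318 in normal colonies, 30316233 to 38145508 in vehicle pools and 39193876 to 41673018 in B[a]P pools. Only 17256 of 3197735 positions were covered at least 10 times in all 24 libraries, so methylation was compared mainly over windows of 1 kb. Genes are not named, because an annotation of the assembly that the coordinates belong to was not used here; regions are given by scaffold, start and end.

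The senescent and bypass cultures addressed how methylation differed before and after escape from senescence. Methylation was higher in the bypass culture at 817 of the 24638 windows tested and lower at 75, so 91.6% of the called windows were higher. The median difference was 26.89 percentage points among windows called higher and -27.91 among those called lower. The windows called higher lay on 207 scaffolds and those called lower on 59. Averaged over all tested windows, methylation was 60.38% ± 0.1688 in bypass and 56.66% ± 0.5261 in senescence (SD, n = 4 technical replicates each). The count of called windows rested on the test: edgeR's quasi-likelihood test called 0 windows in this comparison (smallest adjusted p = 0.0743), with 2686 at an unadjusted p under 0.05 against 4913 for the main test, and a test without squeezing called 170. Of the calls 81.4% were higher over positions shared by the 8 libraries and 64.8% at single positions. Without senescent replicates 1, 3 and 4 the count was 560, 426 and 443, and without bypass replicates 1 to 4 it was 580, 487, 539 and 574.

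Among tested windows, those called higher were more frequent where CpG density was high and where methylation was low, properties that overlapped. Density here means CpG positions measured per window. A call higher needs a rise of at least 10 points, so windows already high in senescence had less room for such a call. This ceiling limits the sparser, more methylated windows more than the dense ones. In the densest quartile, with 31 to 209 positions per window, mean methylation was 37.98% ± 0.4603 in bypass and 31.34% ± 0.3971 in senescence, a difference of 6.642 points, and 456 windows were called higher and 14 lower. In the sparsest quartile, with 3 to 10 positions, the means were 69.5% ± 0.2359 and 68.02% ± 0.3856 (SD, n = 4), a difference of 1.477 points, and 96 windows were called higher and 32 lower. Windows of the densest quartile were called higher more often than the rest of the tested windows (odds ratio 4.064, two-sided Fisher's exact p = 1.45e-82, treating windows as independent). The requirement of 5 to 95% pooled methylation raises this contrast, since it left 6104 of 16317 measured windows of that density and 18534 of 24786 others. Over all measured windows, with untested ones counted as not called, 2.795% and 1.456% were called higher (odds ratio 1.945, two-sided Fisher's exact p = 7.68e-21). The mean differences over all measured windows were 2.733 points (17.61% ± 0.2164 against 14.88% ± 0.1684) and 2.169 points (67.82% ± 0.04305 against 65.65% ± 0.4917, SD, n = 4). Dense windows hold more positions and may be called more easily at the same difference, so neither Fisher test measures the size of a change. In each of the 4 quartiles all bypass libraries lay above all senescent libraries on average (exact two-sided permutation p = 0.02857, the smallest that 70 assignments allow, adjusted p = 0.08571 over 12 tests), which did not pass 0.05 after adjustment.

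Among tested windows measured in all 24 libraries, 8.42% of 4418 were called higher where the 16 libraries outside this comparison averaged under 20%, and 1.189% of 2103 where they averaged 80% or more. Tested windows exclude those under 5% in senescence and bypass pooled, so the first class leaves out windows low in all groups. Windows low elsewhere could enter through a rise in bypass, which can raise the difference and the share called in this class. Within the first class the mean difference was 7.347 points in windows of the densest quartile (18.36% ± 0.5832 against 11.01% ± 0.458) and 7.522 in the others (22.88% ± 0.4449 against 15.36% ± 1.079; SD, n = 4). Of these windows 9.307% and 5.704% were called higher (two-sided Fisher's exact p = 0.000153). The mean differences were alike, so this excess of calls does not show a larger change in dense windows. From 20 to 50% the differences were 9.292 and 5.557 points, with 11.6% and 4.372% called higher (two-sided Fisher's exact p = 7.04e-09). At 50 to 80% and at 80% or more, the shares called higher were 2.349% and 1.327% (two-sided Fisher's exact p = 0.0919) and 1.171% and 1.193% (p = 1), which did not pass; these 4 p-values are unadjusted.

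**Figure D1:**
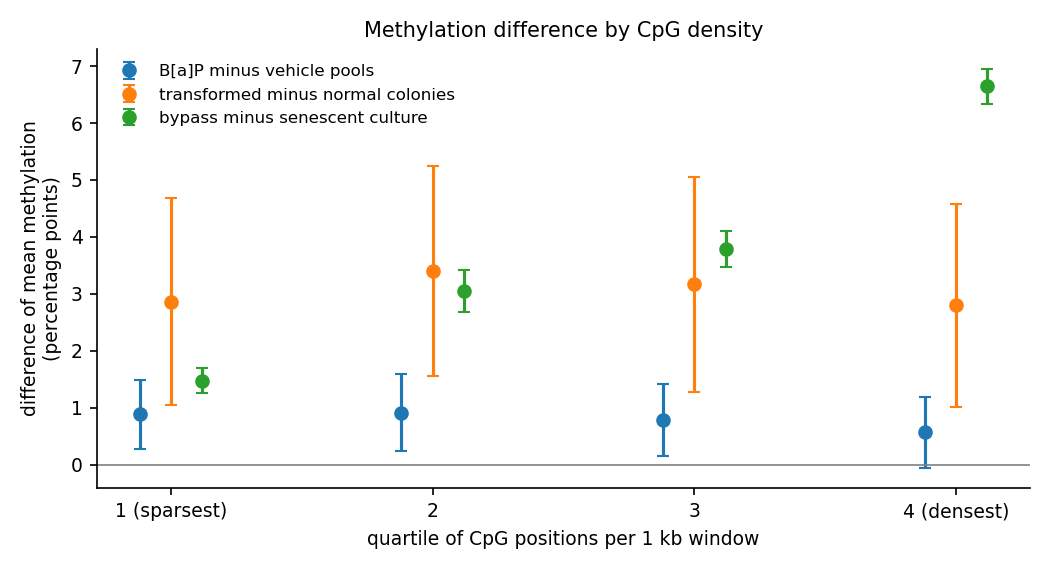
Difference in mean methylation, in percentage points, for each quartile of CpG positions per tested 1 kb window (5 to 95% pooled methylation) in the 3 comparisons. Points are differences of group means and bars their standard errors from 4 libraries per group; in the bypass comparison the difference goes from 1.477 points in the sparsest quartile to 6.642 in the densest.

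The 5 windows with the largest increase, among called windows whose groups did not overlap, rose by 70.26 to 80.24 points. On KB708315.1, positions 1037001 to 1038000, methylation was 80.59% ± 8.292 in bypass and 9.081% ± 4.229 in senescence (SD, n = 4, limma-style squeezed test, adjusted p = 0.000355). It rested on 486 to 906 reads per library, counted once per position they cover, here and below. On KB708274.1, positions 807001 to 808000, it was 77.96% ± 8.375 and 7.707% ± 3.835 (134 to 925 reads; adjusted p = 0.000403). On KB708320.1, positions 1362001 to 1363000, it was 93.19% ± 7.066 and 21.32% ± 5.269. The others, at KB708134.1 from 4431001 to 4432000 and KB708217.1 from 6403001 to 6404000, were at 88.5% ± 15.54 against 11.31% ± 22.19 and 96.82% ± 6.359 against 16.58% ± 24.06. The former was not called without senescent replicate 1, 2 or 4 or bypass replicate 1, 2 or 3 (adjusted p of 0.0516 to 0.0876), and the latter without bypass replicate 1 or 2 (0.0531 and 0.0842) or with thinned reads (0.0525). The 5 largest decreases ran from 48.41 to 83.2 points in size. On KB708337.1, positions 1214001 to 1215000, methylation was 16.8% ± 19.41 in bypass and 100% ± 0 in senescence, from 45 to 195 reads per library; without senescent replicate 4 it was not called (adjusted p = 0.0598). On KB708423.1, positions 453001 to 454000, it was 38.11% ± 12.83 and 95.46% ± 8.581. On KB708181.1 from 2234001 to 2235000, KB708283.1 from 3534001 to 3535000 and KB708199.1 from 10029001 to 10030000 the bypass means were 16.63% ± 7.348, 20.51% ± 10.94 and 38.74% ± 14.31, against 66.13% ± 13.24, 69.47% ± 7.005 and 87.15% ± 4.476 in senescence. Of these 10 windows, 0 were called with edgeR (adjusted p of 0.0743 to 0.259) and 4 without squeezing. KB708217.1 and KB708283.1 are among the scaffolds with lower read coverage in bypass described next.

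Read coverage was lower over part of the genome in the bypass culture. Of 251 scaffolds compared, 10 had a log2 coverage ratio of bypass to senescence under -0.5, between -1.13 and -0.63, while the other 241 lay between -0.23 and 0.23. On 9 of them, spanning 70.5 Mb, 141 of 143 bins of 250 kb were below -0.5, the exceptions being KB708217.1 from 6.0 Mb (0.64) and KB708236.1 from 0 Mb (-0.15). Over these 9 scaffolds coverage relative to the senescent mean was 0.4966 ± 0.01246 in bypass and 1 ± 0.01539 in senescence (SD, n = 4); the scaffolds were chosen by this ratio, so the difference was not tested. The 20 libraries outside bypass lay between 0.9819 and 1.019. On KB708158.1 the change fell inside the scaffold. Its measured bins averaged a log2 ratio of 0.04 ± 0.22 up to the bin starting at 4.5 Mb and -0.98 ± 0.12 (SD over bins) in those starting from 4.75 to 14.25 Mb. These 10 scaffolds held 32 of the windows called higher and 4 of those called lower. Windows called higher made up 4.992% of the 641 tested there and 3.271% elsewhere (two-sided Fisher's exact p = 0.02439, treating windows as independent).

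**Figure D2:**
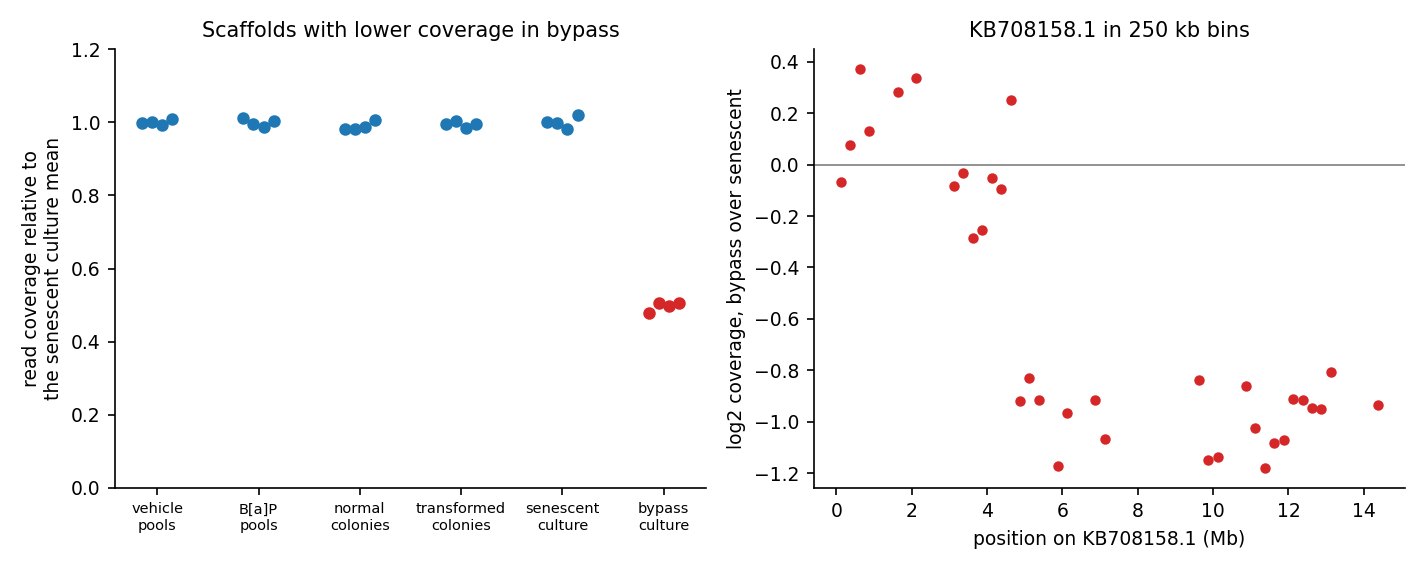
Left, read coverage over 9 scaffolds with lower coverage in bypass, relative to the senescent mean, with 1 point per library. Right, log2 coverage of bypass over senescence along KB708158.1 in bins of 250 kb; the bypass libraries lie between 0.4785 and 0.505 and the other 20 between 0.9819 and 1.019.

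Mean methylation over the 17256 shared positions was 57.15% ± 0.111 in bypass and 55.89% ± 0.5754 in senescence (SD, n = 4), a difference of 1.256 points (exact two-sided permutation p = 0.02857, adjusted p = 0.08571 over 3 comparisons). All 4 bypass libraries lay above all 4 senescent ones, and the difference did not pass after adjustment. With positions weighted by their reads it was 0.2169 points (exact permutation p = 0.7429).

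The windows called between senescence and bypass were then read in all groups, over the windows measured in all 24 libraries. The 580 windows called higher averaged 54.25% ± 0.9046 in bypass and 26.26% ± 0.617 in senescence, the groups that chose them. They averaged 23.9% ± 1.466 in transformed colonies, 21.83% ± 3.304 in normal colonies, 18.99% ± 0.313 in B[a]P pools and 18.86% ± 0.9736 in vehicle pools (SD, n = 4 each). The 39 windows called lower averaged 51.46% ± 2.141 in bypass and 78.33% ± 3.225 in senescence. In the other groups they averaged 65.62% ± 1.615 in transformed colonies, 62.1% ± 4.967 in normal colonies, 69.09% ± 2.206 in B[a]P pools and 64.99% ± 1.421 in vehicle pools.

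**Figure D3:**
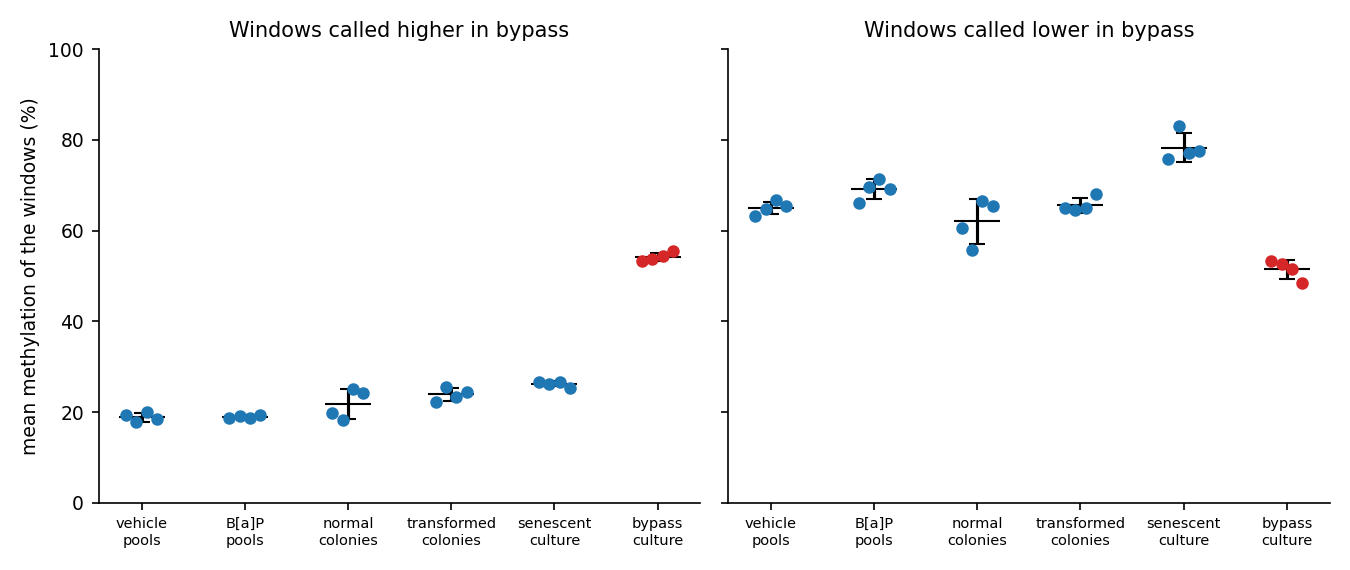
Mean methylation, in percent, of the 580 windows called higher (left) and the 39 called lower (right) in bypass, in each library. Points are libraries, horizontal lines group means and bars the SD of 4 libraries; windows called higher averaged 54.25% in bypass and between 18.86% and 26.26% in the other groups.

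Transformed and normal colonies addressed whether altered morphology went with altered methylation. No window passed the test: 0 of 26825 were called, and the smallest adjusted p was 0.428. Mean methylation over the tested windows was 60.01% ± 1.284 in transformed and 56.97% ± 3.406 in normal colonies (SD, n = 4). Over the shared positions it was 54.75% ± 0.7752 and 52.85% ± 2.575, a difference of 1.898 points (exact two-sided permutation p = 0.2, adjusted p = 0.2), within the spread of the normal colonies. Without normal colony replicate 2, which was at 49.29%, the difference was 0.7098 points, and without normal colony replicate 3 it was 2.745. With positions weighted by their reads it was 4.056 points (exact permutation p = 0.3143).

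The groups did not overlap at 3.1% of the tested windows, where chance gives 2.86%. Among the 5 windows with the smallest p, which did not pass, at KB708292.1 from 528001 to 529000 methylation was 87.64% ± 5.216 in transformed and 26.97% ± 10.63 in normal colonies. At KB708304.1 from 1268001 to 1269000 it was 52.85% ± 9.471 and 13.03% ± 11.04. At KB708344.1 from 280001 to 281000, KB708131.1 from 28761001 to 28762000 and KB708149.1 from 8248001 to 8249000 it was 91.51% ± 3.289, 97.08% ± 2.468 and 98.53% ± 1.161, against 76.43% ± 4.796, 82.63% ± 10.92 and 85.53% ± 25.79 (SD, n = 4). An unadjusted p under 0.05 was reached by 2177 windows, or 8.1%, where 5.81% of unchanged simulated windows reached it, and by 781 in edgeR's quasi-likelihood test, which called 0. Without normal colony replicate 2, 3 or 4 the count was 2, 1 and 1.

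The pools addressed whether B[a]P changed methylation by day 9. Again 0 of 18421 windows were called, and the smallest adjusted p was 0.648. Mean methylation over the tested windows was 60.46% ± 0.4159 after B[a]P and 59.67% ± 1.169 after vehicle. Over the shared positions it was 54.49% ± 0.3161 and 53.49% ± 1.109 (SD, n = 4), a difference of 0.9938 points (exact two-sided permutation p = 0.08571, adjusted p = 0.1286). Without vehicle replicate 2 it was 0.4575 points. Over positions covered in the 8 libraries of the pools it was 0.5239 points (exact permutation p = 0.2857). With positions weighted by their reads it was 1.403 points (exact permutation p = 0.1429).

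Among the 5 windows with the smallest p, which did not pass, methylation at KB708131.1 from 29330001 to 29331000 was 50.24% ± 11.2 after B[a]P and 96.03% ± 7.933 after vehicle. At KB708162.1 from 14218001 to 14219000 it was 14.08% ± 6.839 and 49.4% ± 16.14. At KB708225.1 from 50001 to 51000, KB708134.1 from 2493001 to 2494000 and KB708191.1 from 5615001 to 5616000 it was 93.03% ± 4.703, 98.04% ± 3.926 and 100% ± 0, against 64.49% ± 16.36, 72.91% ± 11.51 and 78.66% ± 12.49 (SD, n = 4). An unadjusted p under 0.05 was reached by 1172 windows, or 6.4%, where 5.86% of unchanged simulated windows reached it, and by 408 in edgeR's quasi-likelihood test, which called 0. On simulated windows with the coverage and squeezed dispersions of these pools, 35% of differences of 40 points and 5% of those of 20 points were recovered. Most simulated differences of these sizes at single windows were thus missed. Without vehicle replicate 1 the count of called windows was 1.

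No called window was shared between comparisons, since calls were made in the bypass comparison alone. The median SD per window between replicates was 4.101 points in bypass (jackknife SE 0.2294), 3.505 in senescence (jackknife SE 0.3028), 3.331 in transformed and 3.498 in normal colonies, 3.506 in vehicle and 3.279 in B[a]P pools. Over windows with at least 5 positions it was 2.625 in bypass and 2.111 in senescence, against 1.578 to 1.72 in the 4 other groups. By another measure the order differed: the median dispersion of the window test was 23.82 in the bypass comparison, 28 in the pools and 39.12 in the colonies.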

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

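The tests of the lower-coverage scaffolds, of shared positions, of 1 uneven library and of the mix of positions in normal colony replicate 2 were chosen after the results were seen. Among 48 groups of 4 values examined for a library far from the rest, 3 stood out, and chance gives about 2.4.

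Read coverage, compared in addition to methylation, was 0.4966 of the senescent level in bypass over 9 scaffolds. Coverage that depends on CpG density is argued against, since the highest log2 ratio over 4 density classes was -0.95. All 4 bypass libraries were low, the highest at -0.99. A single low bypass library could not alone have brought the group mean below -0.5. The choice of scaffolds thus decided the test of 1 uneven library in advance. A candidate explanation, as a hypothesis, is the loss of 1 copy in nearly all cells, which the methylation test left open: 13.37% of 187 windows at 30 to 70% in senescence lay below 20% or above 80% in bypass on these scaffolds, against 13.88% of 6282 elsewhere (two-sided Fisher's exact p = 0.915). The libraries are technical replicates of 1 culture, so whether other cultures share this was not tested.

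For the higher methylation of tested CpG-dense windows in bypass, incomplete conversion was examined in 9174 windows under 2% in the 16 other libraries. Their median rise in bypass was 0.105 points (quartiles -0.3952 and 1.121, mean 0.8164), where at least 5 points were predicted. This argues against a conversion failure of that size. The limit of 5 points exceeds the rise of 2.733 points over all measured dense windows, so a smaller failure was not excluded. Mitochondrial methylation was 1.857 to 3.16% in senescent and 2.633 to 3.819% in bypass libraries. Of the windows called higher 96.08% lay outside the lower-coverage scaffolds, but so did 23997 of the 24638 tested windows, so a high share was set in advance. Leaving these scaffolds out still gave 852 calls, 781 of them higher. The lower-coverage scaffolds thus do not account for most of the higher methylation. Different positions in each library are argued against for 1235 of the 6104 densest-quartile windows, those with enough shared positions. Their mean difference over shared positions, 6.091 points, was 100.6% of that over all their positions. The other windows of the quartile were not compared in this way. Over shared positions 145 of the 817 windows called higher remained called, but only 6976 windows were tested there, against 24638. Only 1 of the 35 splits of the 8 libraries, the real one, called as many as 892 windows with the main test, and the highest other split called 0. This argues against chance within technical spread only, and 1 of 35 is the smallest share possible. Other splits mix the 2 groups, so a difference between the groups raises the spread within each side and lowers the count. At the real split edgeR called 0. A biological difference between day 48 and day 94 may remain, as a hypothesis, but time in culture and bypass cannot be separated in this design.

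Mean methylation of normal colony replicate 2 over its own positions was 23.6%, against 39.78 to 42.18% in the other normal colonies. A different mix of positions is a candidate explanation: over the 289621 positions shared by the normal colonies its deficit was 2.78 points, which is 16.19% of its deficit of 17.17 points over own positions. Over the 17256 positions in all 24 libraries it was 4.754 points, or 27.69%, so a mix of positions leaves part of the deficit. Loss or over-conversion across fully methylated positions is argued against by a median deficit of -1.285 points over windows above 95% elsewhere (quartiles -4.16 and 3.53). The mean deficit was 1.122 points, so loss at some of these windows was not excluded. No other biological explanation was tested.

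Mean methylation over shared positions was 56.75% in senescent replicate 2, against 55.54 to 55.68% in the other senescent libraries. The windows called lower in bypass averaged 68.02% in transformed colony replicate 4, against 64.53 to 65% in the other transformed colonies.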

How the results depend on the processing

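Directions of the mean differences were kept under all alternatives run, and none of these differences passed adjustment. Without single libraries the mean differences ran from 0.4575 to 1.268 points in the pools, 0.7098 to 2.745 in the colonies and 1.138 to 1.542 in bypass. With positions weighted by reads they were 1.403, 4.056 and 0.2169 points, at coverage of at least 20 they were 1.075, 1.994 and 0.8391, and over positions covered in the 8 libraries of a comparison they were 0.5239, 1.727 and 1.745. The number of windows called was less stable. In bypass, against 892, it was 449 at coverage of at least 20, 124 at an adjusted p below 0.01 and 25 points, 8915 with no overdispersion correction, 170 without squeezing, 0 with edgeR, 556 with thinned reads and 416 with the replicate block, and 426 to 719 without single libraries. Over positions shared by the 8 libraries, an alternative chosen after seeing the data, it was 291 of 6976 tested, with 237 higher and 54 lower. Single positions gave 724 calls with another balance, 469 higher and 255 lower (64.8% higher, against 91.6% for windows). Of the 817 windows called higher, 386 remained called at coverage of at least 20, 127 without squeezing, 279 with the block and 145 over shared positions, and the alternatives compared window by window called 0 windows in the opposite direction. Fewer positions, reads or libraries were tested in several of these; for edgeR and the unsqueezed test the cause was not tested, though on simulated windows edgeR recovered 4% of changes of 40 points. In the pools and the colonies, against 0, no overdispersion correction gave 5317 and 9281 windows, on a test that on simulated windows made 5058 and 8353 false calls, and the replicate block gave 2 and 5. Without single libraries the counts were 0 to 1 and 0 to 2. Whether library numbers pair the samples was not decided: 4, 1 and 0 of the 8 libraries of the pools, colonies and bypass comparison correlated best with their own number. All these correlations lay between -0.032 and 0.039, too weak to tell. Of the 10 windows named for bypass, 0 passed with edgeR, 4 without squeezing and 10 with the block, and 7 passed without each single library in turn. The median SD per window with at least 5 positions was 2.111 in senescence, 2.625 in bypass, 1.71 in transformed and 1.72 in normal colonies, 1.682 in vehicle and 1.578 in B[a]P pools. With thinned reads it was 3.537 in transformed and 3.667 in normal colonies. Weighted by reads, windows called higher averaged 22.73% in senescence, 48.25% in bypass, 19.2% in transformed and 17.02% in normal colonies, 15.02% in vehicle and 15.84% in B[a]P pools. Windows called lower averaged 54.65% in bypass, 68.64% in transformed colonies and 66.56% in vehicle pools. Promoter counts and their alternatives were not run, since no annotation of the coordinates' build was used here. Depth and the spread between replicates limit what single windows can show, since most simulated changes of 20 points were missed.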

Other observations

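The test in the colonies was chosen after the result was seen. The 580 windows called higher in bypass averaged 23.9% ± 1.466 in transformed and 21.83% ± 3.304 in normal colonies (SD, n = 4). A hypothesis was that part of the rise may already be present in transformed colonies, and the data did not decide it (exact two-sided permutation p = 0.3143).

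In the pools and in the colonies the real split called 0 windows, so each of the 35 splits of the 8 libraries calls at least as many and the count of splits decides nothing. The highest other split called 1 window in the pools and 2 in the colonies.

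Of the 817 windows called higher in bypass, 413 were under 20% in senescence, 474 were above 50% in bypass, and 81 were both.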
